A study of Micropterus salmoides with 7 samples.

How the data were processed

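Liver RNA of 7 largemouth bass was hybridised to single-colour arrays, 1 array per animal, with 3 control and 4 toxaphene-fed animals. Groups were taken from the sample labels and the replicate numbers only name arrays within a group, so that equal numbers do not pair samples. The labels' protocols name a total RNA extraction and Cy3 labelling by the Agilent one-colour method. Each array's spots were quantified by the authors with Agilent Feature Extraction 10.1.1.1, per the file headers. The processed signal is an intensity on a linear scale, background-subtracted and detrended within the array and not scaled between arrays, per the file headers. The same deposited files give the mean intensity of each spot, its local background, and flags for spots that were saturated, non-uniform, or well above background.

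A second deposited table holds log2 values of the same arrays, and the step that made them is not described in the sources used here. The sample titles carry the prefix Q. Norm., which the labels do not expand. Each of its columns ranked the probes nearly as the processed signal of the same array did, with a Spearman correlation across probes of at least 0.9997. Its columns had medians of 7.00, 7.02, 7.01, 7.02, 7.02, 7.01 and 7.02 for control replicate 1, toxaphene replicates 1 and 2, control replicate 2, toxaphene replicate 3, control replicate 3 and toxaphene replicate 4. Its lowest value was 2.3, shared by 1247 to 1319 probes on an array. A slope of 0.976 to 1.04 against the log2 processed signal places the values on the log2 scale and in the same direction, and the method behind the shared distribution and the floor stays unknown. That table was used as an alternative only.

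For the main results, control spots were removed, leaving 15208 probes with 1 spot each, and log2 of the processed signal was taken. Each array's 75th percentile of these values was subtracted. The 82 spots flagged as non-uniform or as population outliers, over all arrays, were set to missing, and saturated spots were kept. No processed signal was at or below 0. A probe was tested if it was well above background on at least 3 of the 7 arrays, which left 12205 probes, while 10236 probes were well above background on all 7 arrays and 1953 on none. Toxaphene and control arrays were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The test is two-sided. Precision is limited by the number of arrays.

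The procedure was tested on simulated data. In 20 simulated sets of 12205 probes, signals were drawn independently for each probe and array, from the measured means and limma's moderated variances. In each set 200 probes were changed by known amounts. Of changes of 2-fold, 4-fold, 8-fold and 16-fold, 7.6%, 78.1%, 94.6% and 98.7% passed the threshold. A mean of 8.2 unchanged probes was called per set. Slide differences, correlation between probes and the full spread of the probe variances were not simulated.

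The rule for named genes, written before the data were examined, took up to 12 annotated probes in each direction with the smallest p-values, with places filled by probes that did not pass but had a log2 difference of at least 0.58, and a set of named liver and reproductive genes. It needs gene names. All 15208 probes carry the description Unknown, and of their design names (contig numbers for 13699 probes) 0 matched the 37622 genes of the reference table for assembly ASM1485139v1. Another 58 probes carry a name in the form of a sequence record, 29 names in all, and neither the files nor that table gives the gene of those records. The files do not pair probes with gene names, so the text names only the pair of probes in each direction with the smallest p-values and a log2 difference of at least 0.58. The 26 gene lists fixed for liver metabolism, reproduction, stress and cell types could not be matched to any probe, and their tests were not made.

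The array headers placed the arrays on 4 slides and 2 scan days. Slide 1 held control replicate 1 and toxaphene replicate 1, slide 2 held toxaphene replicate 2, slide 3 held control replicate 2 and toxaphene replicate 3, and slide 4 held control replicate 3 and toxaphene replicate 4. Slides 1 and 2 were scanned on day 1, and slides 3 and 4 on day 2. The alternatives tried were normexp background correction (offset 50) of the mean signal and background, quantile normalization, median centring, the deposited log2 table, the slide as a fixed or random block (statmod 1.5.0), array weights, an intensity trend with robust variances, other filters on dim probes, keeping outlier spots, leaving out each array, and the scan day as a block. The scan day was added after seeing the data.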

Results

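Gene expression was measured in the liver of largemouth bass (Micropterus salmoides), a freshwater fish, in animals fed toxaphene and in control animals. Toxaphene is a mixture of chlorinated camphenes formerly used as an insecticide. The series concerns the effects of toxaphene on the liver and gonads, and the liver arrays ask whether feeding the compound altered liver transcript levels. The design text describes the samples as separate animals, with 3 control and 4 toxaphene-fed fish. The sex of the animals is not given per sample. RNA from each animal was labelled with Cy3 and hybridised to an array carrying 15208 probes of 60 bases. Between 11100 probes (control replicate 2) and 12483 probes (control replicate 1) were well above background on an array. The 75th percentile of the processed signal lay between 580.9 (control replicate 3) and 882.7 (toxaphene replicate 3) intensity units. The number of arrays limits the precision of every difference given here.

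The smallest p-values for a difference between toxaphene-fed and control liver belonged to probes that were lower in toxaphene-fed animals, but no probe passed the threshold of an adjusted p of 0.05. The files give every probe the description Unknown and do not pair the probes with gene names, so the leading probes are identified by their array names and sequences. Their values are given as differences that did not pass the test. The probes were picked for their small p-values, and the confidence intervals given for them below were not adjusted for this selection. Those intervals therefore do not have their stated coverage for the picked probes, and they set no lower limit on the differences. The sizes of the differences may be overstated for the same reason. All 4 probes were well above background on each of the 7 arrays, and the control and toxaphene arrays did not overlap for any of them. The direction of the differences within a slide or a scan day was therefore fixed.

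Probe UF_Msa_CF_118209 (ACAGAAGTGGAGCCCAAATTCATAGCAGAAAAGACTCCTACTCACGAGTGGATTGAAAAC) had a log2 signal, relative to the array's 75th percentile, of -1.04 ± 0.66 (SD, n = 3) in control liver and -4.09 ± 0.45 (SD, n = 4) in toxaphene liver. Its mean was 8.29-fold lower in toxaphene-fed animals, with a 95% confidence interval of 4.56-fold to 15.1-fold. The log2 difference was -3.05 ± 0.38 (SE), with an adjusted p of 0.209 in limma. With the slide as a block it was -3.10 ± 0.42 (SE), and with the scan day as a block -3.10 ± 0.40 (SE). Within the 3 slides that held both groups, the log2 differences were -2.27 on slide 1, -4.30 on slide 3 and -2.74 on slide 4. Within scan days they were -2.47 on day 1 and -3.52 on day 2. Normexp background correction moved the median log2 difference of all tested probes to -0.44. With normexp the log2 difference of this probe was -1.71, or -1.28 relative to that median. The main difference rests on low toxaphene signals, at -3.54, -3.94, -4.60 and -4.28 in toxaphene replicates 1, 2, 3 and 4.

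Probe UF_Msa_AF_106745 (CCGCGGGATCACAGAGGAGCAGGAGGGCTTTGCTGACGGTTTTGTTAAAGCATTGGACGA) had a log2 signal of 3.02 ± 0.78 (SD, n = 3) in control and -0.12 ± 0.41 (SD, n = 4) in toxaphene liver, which is 8.82-fold lower (95% confidence interval 4.68-fold to 16.6-fold). The log2 difference was -3.14 ± 0.40 (SE), with an adjusted p of 0.209 in limma. It was -3.18 ± 0.47 (SE) with the slide as a block and -3.16 ± 0.43 (SE) with the scan day as a block. Within slides 1, 3 and 4 the log2 differences were -2.24, -4.54 and -2.78, and within scan days 1 and 2 they were -2.41 and -3.66. With normexp it was -2.37, or -1.93 relative to the median of all tested probes.

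The pair of probes with the smallest p-values among those higher in toxaphene-fed animals had smaller differences. Probe UF_Msa_AF_107272 (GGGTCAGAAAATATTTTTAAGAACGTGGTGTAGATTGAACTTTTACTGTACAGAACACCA) had a log2 signal of -4.67 ± 0.79 (SD, n = 3) in control and -2.56 ± 0.07 (SD, n = 4) in toxaphene liver. Its mean was 4.33-fold higher (95% confidence interval 2.45-fold to 7.65-fold), with a log2 difference of 2.12 ± 0.36 (SE) and an adjusted p of 0.435 in limma. With normexp background correction its sign was negative, at -0.50, or -0.07 relative to the median of all tested probes. The main difference rests on low control signals, at -5.49, -3.91 and -4.62 in control replicates 1, 2 and 3. With the slide as a block the log2 difference was 2.09 ± 0.33 (SE), and with the scan day as a block 2.20 ± 0.34 (SE). It was 2.84, 1.35 and 2.07 within slides 1, 3 and 4, and 2.93 and 1.71 within scan days 1 and 2.

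Probe UF_Msa_CF_122979 (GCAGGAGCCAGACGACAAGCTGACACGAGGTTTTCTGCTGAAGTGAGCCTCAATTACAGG) had a log2 signal of -0.48 ± 0.46 (SD, n = 3) in control and 1.32 ± 0.40 (SD, n = 4) in toxaphene liver. Its mean was 3.49-fold higher in toxaphene-fed animals (95% confidence interval 2.10-fold to 5.78-fold), with a log2 difference of 1.80 ± 0.32 (SE) and an adjusted p of 0.435 in limma. With the slide as a block it was 1.94 ± 0.25 (SE), and with the scan day as a block 1.75 ± 0.33 (SE). It was 1.92, 2.34 and 1.56 within slides 1, 3 and 4, and 1.45 and 1.95 within scan days 1 and 2. With normexp it was 1.13, or 1.57 relative to the median of all tested probes.

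**Figure D1:**
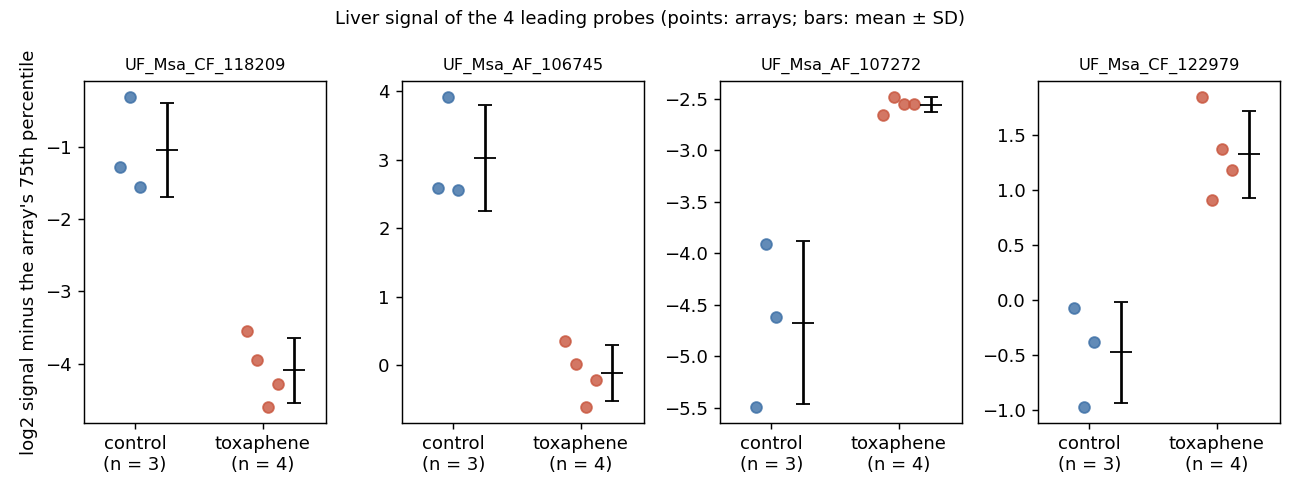
Log2 signal minus the array's 75th percentile (vertical axes, scaled separately for each probe) for the 4 leading probes in control (blue, n = 3) and toxaphene (red, n = 4) liver. Points are arrays and black bars are the mean and SD. The control and toxaphene arrays do not overlap for any of these probes, and none of the differences passed an adjusted p of 0.05.

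Across the 12205 probes tested, 0 had an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.209. At an unadjusted p under 0.05 there were 481 probes, of which 245 were higher and 236 lower in toxaphene-fed animals. The even division depends on the scaling, since 50.9% of these probes were higher in the main setting and 35.5% of those found with median centring. The 481 probes were 3.94% of the probes tested, where 610.2 probes would be expected with no difference at all. This count depends on the processing, from 151 with normexp background correction to 951 with the slide as a fixed block. It can thus fall on either side of the expected number. At an unadjusted p under 0.001 there were 20 probes, 7 higher and 13 lower, against 12.2 expected. No other test tool was run on these values.

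Differences of 2-fold or more in the group means were seen for 227 probes higher and 188 probes lower in toxaphene liver, and differences of 4-fold or more for 26 higher and 20 lower. None of these differences passed the adjusted threshold in limma. The 95% confidence interval of a probe's log2 difference had a median half-width of 0.74. For 49.2% of the probes the interval lay within 2-fold in either direction, and for 92.3% it lay within 4-fold, so larger changes are excluded for those probes one at a time. For the remaining probes the data do not exclude a change of that size. Simulated arrays of the same group sizes had 200 of 12205 probes changed at once, with independent noise at limma's moderated variances. There, 7.6% of 2-fold changes, 78.1% of 4-fold changes and 94.6% of 8-fold changes passed the threshold. The adjusted threshold is stricter where fewer probes change, so recovery of sparse changes would be lower and was not simulated. Moderated variances are also drawn toward a common value and spread less than the variances of the probes themselves. The recovered shares may therefore be overstated.

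The control and toxaphene arrays did not overlap for 648 of the 12147 probes with a value on each array, which is 5.33%, where 5.71% is the share that chance gives for 3 arrays against 4. A total of 8 probes were well above background on all arrays of 1 group and on no array of the other. Over the 35 splits of the 7 arrays into 3 and 4, the median of that count was 15.

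Correlations between arrays were about as high across the groups as within them. Over the 12147 probes, Pearson's r between arrays averaged 0.961 for the 9 pairs within a group and 0.964 for the 12 pairs between groups. Arrays that shared a slide were always of different groups, with r of 0.976 (slide 1), 0.967 (slide 3) and 0.976 (slide 4). The comparison therefore mixes group with slide. These correlations are across probes, which are not independent replicates. The first principal component held 33.0% of the variance between arrays, and 5.97% of its own variance lay between the groups. It set toxaphene replicate 2, at a score of 72.3, apart from the other arrays, whose scores lay between -39.5 and 17.9. The second component held 22.6% of the variance, with 3.99% of it between the groups. The third component held 15.7%, with 62.4% of it between the groups. On this component control replicates 1, 2 and 3 scored -0.77, 50.8 and 16.2, and the toxaphene arrays between -26.4 and -10.4. Its share between the groups thus leans on control replicate 2, and was not compared with other splits of the arrays.

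**Figure D2:**
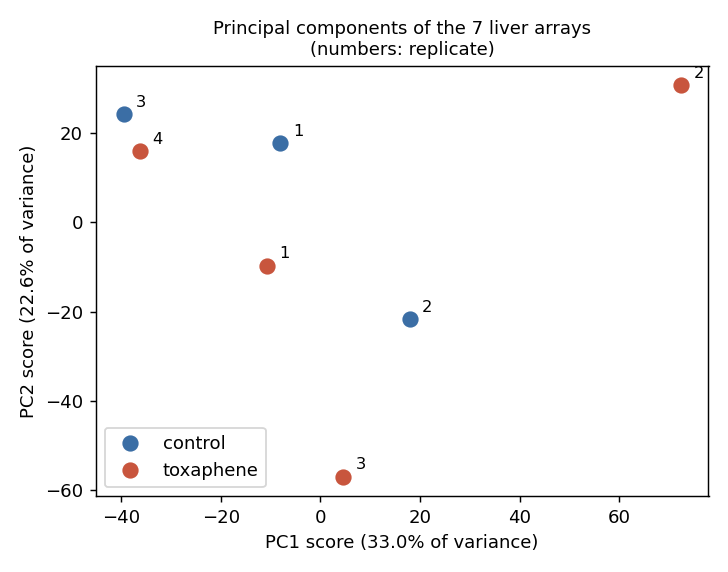
Scores of the 7 liver arrays on the first (horizontal, 33.0% of the variance) and second (vertical, 22.6%) principal components of the log2 signals, in score units. Blue points are control and red points toxaphene arrays, and the number beside each point is the replicate. Toxaphene replicate 2 lies alone at the right, with a first-component score of 72.3, and the groups are intermixed along both axes.

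Some probes stood out on the arrays of slide 3, where the slide cannot be told apart from a difference between its animals. On slide 3, which held control replicate 2 and toxaphene replicate 3, a set of 13 probes was at least 8-fold lower on both arrays than on each of the other 5 arrays. The median log2 signal of these probes was -2.61 in control replicate 2 and -2.47 in toxaphene replicate 3. It was 2.76 and 2.24 in control replicates 1 and 3, and 1.75, 2.95 and 2.32 in toxaphene replicates 1, 2 and 4. All 13 probes were well above background on every array. Their median log2 difference between toxaphene and control was 0.16. No probe among the 12147 tested probes with a value on each array was 8-fold apart in this way between control and toxaphene animals. The set was chosen as low on 1 array of each group, so neither value tests an effect of toxaphene on these probes.

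**Figure D3:**
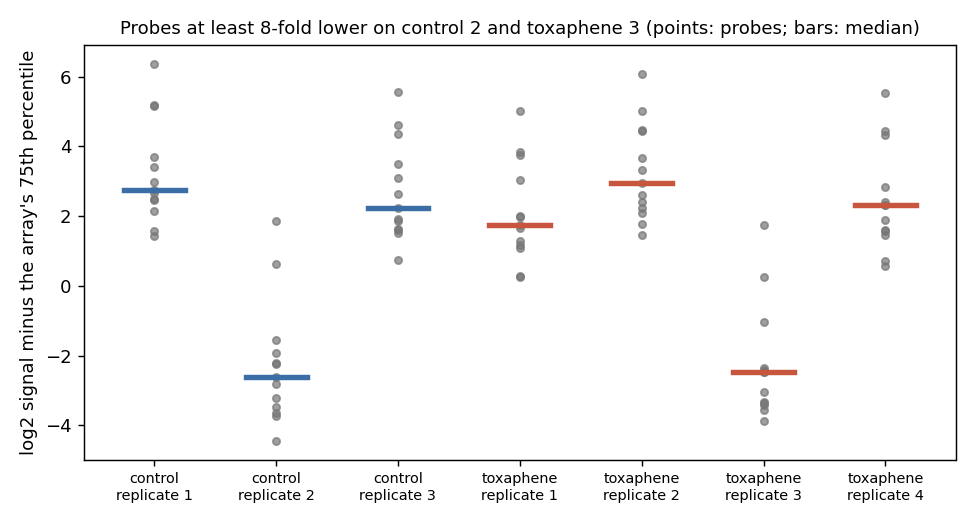
Log2 signal minus the array's 75th percentile (vertical axis) of the 13 probes at least 8-fold lower on both arrays of slide 3, for each of the 7 arrays (horizontal axis). Points are probes and horizontal bars are the array's median (blue control, red toxaphene). Control replicate 2 and toxaphene replicate 3 have medians of -2.61 and -2.47, and the other arrays lie between 1.75 and 2.95.

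Blocking by slide or scan day brought no probe past the adjusted threshold. With the scan day as a block, 0 probes passed the adjusted threshold and 415 had an unadjusted p under 0.05, and with the slide as a block these counts were 0 and 951. The fixed block for the slide compares arrays within slides, so toxaphene replicate 2, alone on slide 2, does not enter its differences, which rest on 3 control and 3 toxaphene arrays. Leaving that array out with no block gave 699 probes at an unadjusted p under 0.05. Within scan day 1, with 1 control and 2 toxaphene arrays, 0 probes passed and 172 had an unadjusted p under 0.05. Within scan day 2, with 2 control and 2 toxaphene arrays, 0 probes passed and 424 had an unadjusted p under 0.05. With so few arrays in a day, and a lone control array on day 1, a count of 0 within a day does not bear on whether probes differ. A slide held at most 1 array of each group, so no test was made within a slide.

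**Figure D4:**
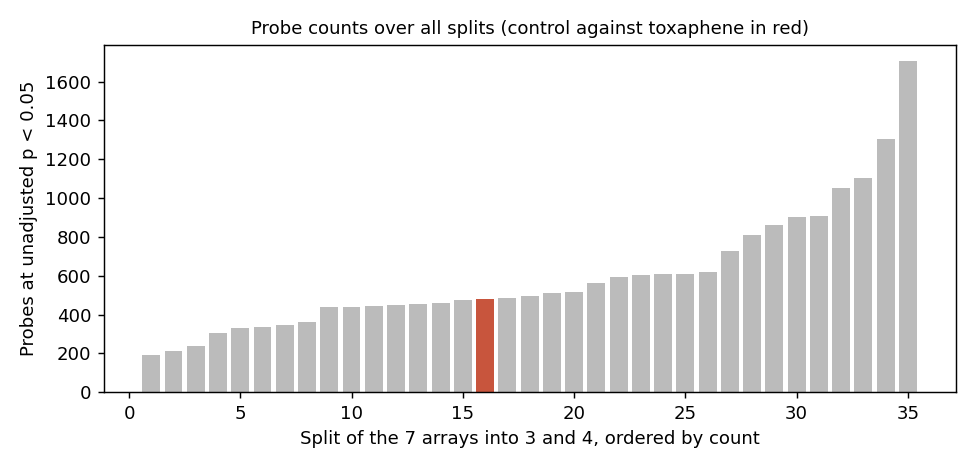
Number of probes at an unadjusted p under 0.05 (vertical axis) for each of the 35 splits of the 7 arrays into 3 and 4 (horizontal axis, ordered by count). The red bar is control against toxaphene, with 481 probes, and the grey bars are the other splits, which range from 192 to 1705 probes.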

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

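Of the tests in this part, the dim-spot, normalization and surface tests of toxaphene replicate 2, the splits of the arrays and the swaps within slides were written before their results were seen, and the slide, surface and feeding tests of the probes on slide 3 were chosen after the result was seen. Among the 4 toxaphene arrays, the 75th percentile of the processed signal was far from the others in toxaphene replicate 3, at 882.7 intensity units, with a gap to the nearest array of 0.871 of the group's range, above Dixon's 95% critical value. Of the 10 quantities examined this way it alone passed, and chance passes about 1 in 20. The main scaling divides this level out.

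With 0 probes past the adjusted threshold for the real groups, a count as high in 35 of the 35 splits into 3 and 4 is fixed in advance and decides nothing, and the highest of the other splits gave 2. At an unadjusted p under 0.05 the real groups gave 481 probes, 20 of the 35 splits gave as many, and the highest other gave 1705, so chance is not excluded for this count without a block. A split that calls several times the real count may reflect a structure of the samples. The split with 1705 probes keeps the slides whole, with slides 2 and 3 against slides 1 and 4. But the other splits that do so gave 454 and 442, and splits that break slides gave up to 1304. The arrays of slides 2 and 3 also had the highest first-component scores. These were 72.3 for toxaphene replicate 2, 17.9 for control replicate 2 and 4.52 for toxaphene replicate 3. The scores come from the same signals, so they do not identify a source. With the slide as a block, which also drops toxaphene replicate 2 from the difference, the real groups gave 951 probes, against 610.2 expected with no difference and 699 without that array and with no block, and the highest of the other swaps of the labels within slides gave 609. There are 4 such swaps, the real one included, of which 1 gave as many as 951, and these are too few for a share under 0.05.

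Toxaphene replicate 2 lay farthest from the other arrays, with a median absolute log2 deviation of 0.44 from the mean of the others, against 0.36 for the next array. Quantile normalization left it at 1.31 times the next array, which argues against unequal scaling across intensities. Over the probes with a mean signal above the median it was 1.04 times the next array, and over the dimmer probes its deviation was 0.61 against 0.43, so dim spots may account for part of the distance. Regions of the array surface held 12.1% of the variance of its deviations, but 11.4% for control replicate 3, which decides nothing. It was alone on slide 2 and held 39 of the 82 outlier spots. Its spike-in control spots had a median coefficient of variation of 12.2%, against 11.7% for control replicate 2 and at most 6.41% elsewhere. Control replicate 2 nevertheless deviated by 0.32. Technical noise, slide and animal therefore cannot be told apart for toxaphene replicate 2.

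The 13 probes at least 8-fold lower on both arrays of slide 3 stand out among divisions of the arrays, since the highest count of probes lower on any other pair of arrays was 1. The low arrays hold 1 animal of each diet, so the count of 0 probes 8-fold apart between the diets was fixed for this set and toxaphene feeding was not tested by it. A region of the array surface is argued against, since the fullest of 16 regions held 23.1% of the spots. The count of 13 along slide 3 leaves the slide open. The slide cannot be told apart from a difference between these animals, since it holds no other array of the series. A difference of sex between the animals was not tested, because sex is not given per sample. Over the other 5 arrays the probes varied together, with a median pairwise r of 0.855 across arrays, above the highest of 1000 random sets at 0.409, which is consistent with the probes sharing a source.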

How the results depend on the processing

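No probe had an adjusted p under 0.05 in limma under any of the 19 alternatives, with lowest adjusted p-values between 0.0780 and 0.646. At an unadjusted p under 0.05 the count was 481, and it stayed within 1.5 times of this under 15 of the 19 alternatives. It was 151 with normexp background correction, 951 with the slide as a fixed block, 783 with the slide as a random block and 833 with array weights. The fixed block leaves toxaphene replicate 2 out of the difference, and the count without that array and with no block was 699, so the block and the loss of that array are mixed in it. The causes were otherwise not tested. Leaving out each array in turn gave 0 probes past the adjusted threshold each time and between 362 and 711 at an unadjusted p under 0.05. Of the 481 probes 50.9% were higher in toxaphene, and median centring gave 35.5%. Normexp moved the median log2 difference of all tested probes to -0.44, from 0.00 in the main setting. Under it the difference of UF_Msa_AF_107272 turned to -0.50 (adjusted p 0.451), which is -0.07 relative to that median; the cause was not tested. The other 3 named probes kept their direction under all 19 alternatives. These probes have no overlap between the groups, so leaving out an array, or blocking by scan day or fixed slide, could not reverse them. Their log2 differences ranged from -3.30 to -1.71 for UF_Msa_CF_118209 and from -3.38 to -2.37 for UF_Msa_AF_106745, the difference of UF_Msa_CF_122979 was at least 1.13, and none passed the threshold. The alternatives for gene lists and the use of 1 value per gene were not run, because neither the files nor the reference table paired a probe with a gene. The replicate numbers follow the order of the samples and pair nothing, so the slide was the only pairing fitted. The scan day as a block was chosen after seeing the data. Signal over background limits the probes tested, since 1953 probes were well above background on no array.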

Other observations

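The test of the leading probes was chosen after the result was seen. The 20 probes with an unadjusted p under 0.001 held more strongly correlated pairs within the groups than random sets of probes did. Of their 190 pairs, 11 pairs or 5.79% had a correlation above 0.9 of the deviations from the group means, against a median of 1.05% and a 95th percentile of 2.63% in 1000 random sets of probes. None of the 20 probes had the same sequence as another. For UF_Msa_CF_118209 and UF_Msa_AF_106745 this correlation across the 7 arrays was 0.979. Some of these probes may therefore share a source of variation, and their number may overstate the number of separate differences. The probes were picked by p-values from the same arrays, and probes that vary together can enter such a list together. The correlations do not tell shared transcripts or shared regulation from differences between arrays or animals. The sequences were not placed on a genome, so which of these applies was not tested.

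Spots that repeat a sequence measure the spot noise within an array, and not the labelling, hybridisation or slide differences between arrays. A set of 53 sequences was spotted under a pair of names each, and both spots were well above background on all arrays for 44 of them. The median absolute difference between such spots on 1 array was 0.10 on the log2 scale, and the median SD between arrays of a group was 0.43 for the same sequences. The toxaphene minus control differences of paired spots were a median of 0.05 apart, and at most 1.12.

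The design holds 197 pairs of probes whose names differ by an ending that reads rc, and 2 of them were exact reverse complements. Both members were well above background on all arrays for 111 pairs, 1 member was for 54 pairs, and neither was for 32 pairs. The members were mostly far apart in mean signal, over 4-fold for 163 pairs and over 16-fold for 132. The median gap was 6.51 on the log2 scale. For 18 pairs 1 member was well above background on all arrays and the other on none.

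Among the 321 probes of this name class with a value on each array and enough signal for the test, 68.2% were lower in toxaphene-fed than in control animals. Over the 35 splits of the arrays into 3 and 4, 13 splits gave a share as far from an even division, so this one-sided share is within what other splits give.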
